A study of Mus musculus with 4 samples.

How the data were processed

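Droplet single-cell RNA sequencing libraries from lung leukocytes of tumour-bearing mice were analysed. Per the labels' protocols, Balb/c mice received an intravenous injection of 4T1 cells, a mouse mammary carcinoma line that seeds the lung from the blood, either wild type or with PD-L1 knocked out. The lungs were perfused and taken 14 days later, digested with collagenase and enriched for cells bearing CD45, the pan-leukocyte surface marker, with magnetic beads. Libraries were made with the 10x Genomics 3' kit, version 3, and sequenced on a NextSeq 500 with a 28 bp first and a 91 bp second read, per the series' design text. In units of 1000, that text states 30 to 39 reads per cell and 2.3 to 2.7 cells per sample, and a median of about 1600 genes per cell. Reads were mapped to mm10 by STAR within Cell Ranger 3.1.0, per the submitters' processing notes; the annotation release is not given in the sources used here.

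The deposited matrices hold whole-number UMI counts per gene and cell barcode, per the file headers and the values, with no normalization. A UMI (unique molecular identifier) marks 1 captured RNA molecule, so that PCR copies of a molecule are counted once. The matrices held 10382 barcodes in all and 2370 to 2736 per library, with 17618220 to 19635984 UMIs. The least UMIs of any barcode were 500 to 502 per library, so barcodes below about that number are not analysed here. At most 3 barcodes were shared by any pair of libraries. The kit reads the 3' ends of transcripts, so isoforms are not told apart and a deletion elsewhere in a gene need not lower its count.

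The 4 libraries were grouped by the sample labels into 2 labelled WT and 2 labelled PD-L1 KO, numbered 1 and 2 in the titles. The names of the deposited files carried the opposite condition for both groups: the samples labelled WT had files named as knockout. The labels were used as given, and every direction in the text rests on them. The labels do not say whether the libraries came from separate mice, so p-values for single genes and class shares measure only the spread between these libraries, which may be technical.

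Barcodes with fewer than 200 genes or more than 10% mitochondrial UMIs were left out (1126 barcodes), as were the barcodes with the highest Scrublet doublet scores (scanpy 1.11.5) in each library, at a rate of 0.8% per 1000 barcodes. That rate marked 216 barcodes, 2.08% of all, and 9054 cells were kept. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were chosen without interferon-response, ribosomal and mitochondrial genes, and 30 principal components and 15 neighbours fed Leiden clustering (leidenalg 0.10.2) at resolution 1 with seed 1. The 33 clusters were named from marker genes fixed before the data were examined, and a class name followed by "-like" stands for cells of such clusters. A cluster stayed unnamed when a second lineage's markers reached a level of 0.1 and at least 0.33 times that of the first lineage, or when fewer than 5 markers of its class were detected in 25% of its cells. These limits were set, and revised once, after the clusters had been seen. They kept out 6 clusters of mixed lineages with 1161 cells, a share of 12.9% ± 1.77 (SD, n = 2) in the libraries labelled WT and 12.8% ± 2.13 (SD, n = 2) in those labelled PD-L1 KO. Mean shares of clusters 10, 11, 15 and 19 were lower in the latter. Those of clusters 20 (1.24% ± 0.203 against 2.36% ± 0.592) and 27 (0.707% against 1.23%) were higher. Cluster 20 was led by histone genes and Mki67, and its closest class was T cell. Its cells are thus missing from the T-like shares and sums. A further cluster with too few markers held 0.859% and 0.556%, respectively. Doublets of cells of 1 lineage are not found by these steps.

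Counts were summed per library over all kept cells and over each class with at least 20 cells in every library, because cells are not replicates. These fits overlap, as all use the same libraries, whole libraries hold every class and T-like cells hold the CD8 T-like ones. Numbers of fits that go one way are therefore not independent results. Genes were kept with filterByExpr, scaled with TMM and tested by edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with the group as the single factor and Benjamini-Hochberg adjustment within each fit, at an adjusted p of 0.05. With 2 libraries against 2 there were 2 residual degrees of freedom before the spread was shared over genes. Log2 differences are libraries labelled PD-L1 KO minus libraries labelled WT, CPM is the usual scaling of summed counts to their library total, and ± is the SD over n = 2 libraries. Cells per class were tested with the same model, with all kept cells as the library size and no further scaling. An exact permutation test of 2 against 2 libraries has 3 splits, and its smallest two-sided p is 0.333.

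Gene lists fixed before the data were examined were tested with limma 3.58.1's camera on voom values of the same sums, with a preset correlation between genes of 0.01 and adjustment over all pairs of list and fit. With a preset correlation, camera ranks a list's members against the other genes. Its p-values do not measure the spread between libraries, and a small one is not evidence at the level of replicates. The 21 lists were the type I interferon response; interferon-gamma-inducible GTPases and regulators; type I interferons, their sensing and receptor; MHC class I presentation; MHC class II presentation; T cell recruiting chemokines and their receptors; myeloid chemokines and their receptors; cytotoxic effectors; checkpoint receptors and ligands; inflammatory cytokines and NF-kB targets; neutrophil granule and maturation genes; suppressive and alternatively activated myeloid genes; glycolysis; oxidative phosphorylation; proliferation; immediate early and heat shock genes; haemoglobin and erythroid genes; lung epithelial secretory genes; immunoglobulins; ribosomal proteins; and mitochondrial transcripts. A list with fewer than 3 members in a fit was not tested there. The test was repeated with a correlation estimated from the data, and with fry, which asks whether a list's genes move, on balance, one way. Over the 165 pairs of list and fit, 99 passed with the preset correlation, 0 with an estimated correlation (smallest adjusted p = 0.515) and 1 with fry.

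The genes named in each fit were chosen by a rule set before the data were examined. It took up to 10 genes higher and 10 lower with the smallest adjusted p among those past the threshold whose libraries of 1 group both lay beyond both of the other group. Where fewer than 3 passed, it took the 6 genes with the smallest p, which are said not to pass. It added up to 4 members of each list with the smallest p, and a fixed set followed in every fit, among them Cd274, Pdcd1, Ifnar1, Irf7, Isg15, Cxcl10 and Gzmb. From these, the text names a part, and results for some genes are not reported here.

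The edgeR step was tested on simulated counts drawn from the real means and library sizes, with 100 genes changed by 2-fold and 100 by 4-fold. Over the 9 fits, 35% to 72% of the 2-fold and 78% to 97% of the 4-fold changes were recovered, and 4.32% to 13.6% of the calls were false. With no gene changed, 9 calls were made in alveolar macrophage-like, 2 in dendritic-like and 1 in monocyte/macrophage-like sums, and 0 in the other 6 fits. A simulated 4-fold change in a class share was recovered in 66% of 100 draws. Counting limits are exact Poisson intervals at 95%, a count of 0 allows up to 3 counts, and both cover counting error only. Gene positions are from GENCODE mouse release 21 for mm10; 30934 of 31053 gene IDs in the files matched it.

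The alternatives set before the data were examined were DESeq2 1.42.0, its size factors within edgeR, no filter on low counts, every class thinned to the smallest library's number of cells, no cell filter, a stricter one (500 genes, 5% mitochondrial), doublets kept, the excluded genes kept in clustering, Leiden resolutions 0.5 and 2, TMM on the class shares, the replicate number as a block, and each library left out in turn. Those added after the data had been seen were a crossed pairing, leukocyte clusters alone, clustering without differing genes, clusters fitted on their own and removal of cells rich in macrophage UMIs.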

Results

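Gene expression was measured in single leukocytes from the lungs of mice carrying 4T1 mammary carcinoma cells in the lung, injected 14 days earlier as wild-type cells or as cells lacking PD-L1, the ligand of the inhibitory receptor PD-1. The comparison asks how immune cells around tumour cells without PD-L1 differ, with the type I interferon response and cytotoxic T cells among the stated interests of the study. There were 2 libraries labelled WT and 2 labelled PD-L1 KO. Library 1 labelled WT held 2736 barcodes and 18573034 UMIs, and library 2 held 2699 and 19338260. Library 1 labelled PD-L1 KO held 2577 barcodes and 19635984 UMIs, and library 2 held 2370 and 17618220. After filtering 2451, 2364, 2220 and 2019 cells were kept, in the same order, with medians of 4411, 4618, 5101 and 5512 UMIs per cell. The share of barcodes failing the filter was 8.3%, 10.5%, 11.9% and 13%. The libraries labelled PD-L1 KO held fewer barcodes and more UMIs per cell.

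Cd274, the gene of PD-L1 (chromosome 19, 29367455 to 29388095, plus strand, mm10; ENSMUSG00000016496), is expressed by myeloid cells of the host as well as by tumour cells. Over all kept cells it had 520 UMIs (30.1 CPM, 95% counting limits 27.6 to 32.8) in library 1 labelled WT and 417 (23.2 CPM, 21 to 25.5) in library 2. It had 839 UMIs (46.3 CPM, 43.2 to 49.5) in library 1 labelled PD-L1 KO and 637 (38.8 CPM, 35.8 to 41.9) in library 2. The log2 difference was 0.73 (SE 0.20), which did not pass edgeR's quasi-likelihood test (Benjamini-Hochberg adjusted p = 0.750). Among cells selected for CD45, 14 carcinoma-like cells were found, 5 and 1 in the libraries labelled WT and 5 and 3 in those labelled PD-L1 KO. They held 0, 6, 2 and 1 UMIs of Cd274, too few to check the labels, and a knockout need not remove the 3' tag that is counted. The 1 such cell of library 2 labelled WT also held 24 UMIs of Ptprc, the gene of CD45, and 29 of Xist, but 0 of Epcam, an epithelial gene. Carcinoma-like cells of the other libraries held 2, 1 and 2 UMIs of Ptprc, 0 of Xist, and 30, 246 and 91 of Epcam.

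Clusters were named as 13 classes with at least 50 cells, and none passed the test for a different share in the labelled groups. Monocyte/macrophage-like cells made up 13.4% ± 1.33 (SD, n = 2) of kept cells in the libraries labelled WT and 18.3% ± 0.291 (SD, n = 2) in those labelled PD-L1 KO (log2 difference 0.44, SE 0.49, edgeR adjusted p = 0.980). CD8 T-like cells made up 6.05% ± 0.536 and 5.82% ± 2.28 (log2 difference -0.05, SE 0.50, adjusted p = 0.988). NK-like cells made up 5.88% ± 1.67 and 5.25% ± 0.285 and B-like cells 7.66% ± 0.245 and 6.98% ± 2.87. Shares were 14.9% ± 5.08 and 16.3% ± 4.86 for neutrophil-like cells, and 11.3% ± 3.41 and 11.2% ± 1.25 for alveolar macrophage-like cells. Plasmacytoid dendritic-like cells, which are specialised in making type I interferon, had the smallest p, at 0.969% ± 0.592 and 2.16% ± 0.445 (log2 difference 1.15, SE 0.56, adjusted p = 0.645, exact permutation p = 0.333, the smallest possible). Their log2 difference was 1.96 without library 1 labelled WT, 0.64 without library 2, 1.35 and 0.92 without libraries 1 and 2 labelled PD-L1 KO. Endothelial-like cells, which are not leukocytes, made up 6.41% and 14.5% in the libraries labelled WT and 7.16% and 6.04% in those labelled PD-L1 KO. By edgeR, 0 of 13 classes passed and 1 had an unadjusted p under 0.05.

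**Figure D1:**
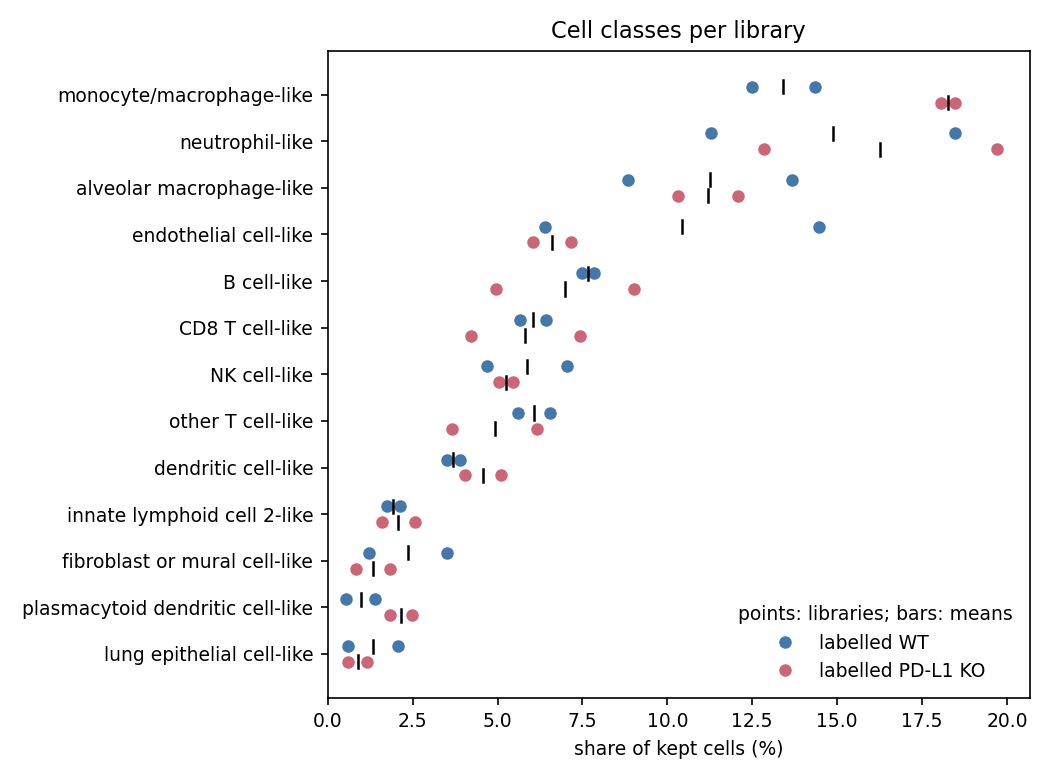
Share of kept cells (x axis, %) per cell class (y axis); points are single libraries coloured by label and bars are means of 2 libraries. Points of the labelled groups overlap in 10 of 13 classes and not in the monocyte/macrophage-like (13.4% against 18.3%), dendritic-like (3.70% against 4.58%) and plasmacytoid dendritic-like (0.969% against 2.16%) classes, and no class passed the test.

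Over whole libraries no gene passed the test, and Ifit2, Rsad2, Ifit3 and Hspa1b had the smallest p. Ifit2, an interferon-induced inhibitor of viral translation, stood at 17.6 CPM ± 0.534 (SD, n = 2) in the libraries labelled WT and 36.1 ± 2.12 in those labelled PD-L1 KO (log2 difference 1.10, SE 0.11). Rsad2, the antiviral enzyme viperin, stood at 34.5 ± 2.28 and 64.1 ± 0.0118 (log2 0.95, SE 0.12), and Ifit3 at 16.2 ± 1.66 and 32.8 ± 3.81 (log2 1.08, SE 0.14). Hspa1b, an inducible heat shock chaperone with a near-identical copy in Hspa1a, stood at 13.8 ± 0.0779 and 6.66 ± 0.0573 (log2 -0.99, SE 0.14). All 4 had an edgeR adjusted p of 0.750. By edgeR, 0 of 13990 genes passed and 543 had an unadjusted p under 0.05, where chance gives 700. DESeq2 called 11 higher and 4 lower. Without library 1 labelled WT 2258 genes passed, without library 2 48, and without either library labelled PD-L1 KO 0. Both libraries labelled PD-L1 KO lay above both labelled WT for 15% of genes and below for 26.4%, where chance gives 16.7% each way. Leukocyte clusters held 2232, 1860, 1972 and 1858 of the kept cells of WT 1, WT 2, PD-L1 KO 1 and PD-L1 KO 2. Over these cells alone, a setting chosen after the data had been seen, 0 of 12702 genes passed by edgeR, 1468 had an unadjusted p under 0.05 (635 by chance), and DESeq2 called 81 higher and 9 lower.

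In 7 of 9 fits, which overlap in cells and share the same libraries, the type I interferon response list ranked higher in the libraries labelled PD-L1 KO. Its median log2 difference was 0.56 in whole libraries (64 of 64 members higher, limma camera adjusted p = 8.19e-36) and 0.94 in alveolar macrophage-like cells (54 of 54, adjusted p = 1.0e-37). The median was 0.66 in dendritic-like cells (52 of 54, 9.25e-31) and 0.58 in monocyte/macrophage-like cells (60 of 62, 1.64e-32). It was 0.59 in NK-like cells (30 of 32, 9.76e-14), 0.43 in CD8 T-like cells (36 of 42, 7.62e-12) and 0.38 in T-like cells (44 of 46, 6.94e-13). All 7 calls were lost with an estimated correlation (adjusted p = 0.515 with an estimated correlation in each). In neutrophil-like cells the median was -0.06 (17 of 40 members higher, adjusted p = 0.599) and in B-like cells 0.07 (21 of 34, adjusted p = 0.451). The difference between classes was not tested here. Over the 9 fits, 175 member values passed adjusted over the list alone, all higher, and 9 passed over all genes tested. All 7 calls held without each library in turn. The CD8 T-like call was lost with no cell filter (0.10, adjusted p = 0.056) and with interferon, ribosomal and mitochondrial genes kept in clustering (0.02, 0.251). Those settings tested another, smaller set of cells. The class held 68, 95, 76 and 38 cells in the first and 61, 90, 64 and 30 in the second, against 139, 152, 165 and 85. It was made of cluster 9 (76, 59, 100 and 53 cells), led by Cxcr6 and Pdcd1, and cluster 12 (63, 93, 65 and 32). Dapl1 and Lef1 were among the leading genes of cluster 12. The smaller sets had about the cell numbers of cluster 12 alone, so their values need not be those of the whole class. Which cells they held was not checked. The T-like median was 0.77 and 0.21 without libraries 1 and 2 labelled PD-L1 KO, and the CD8 T-like median 0.67 and 0.28. The list of type I interferons, their sensing and receptor had a median of 0.16 in whole libraries (adjusted p = 0.019; adjusted p = 0.515 with an estimated correlation). It was not past without library 2 labelled WT (0.08) or over leukocyte clusters alone (0.07), and was 0.28 without library 1 and 0.10 without library 2 labelled PD-L1 KO. It passed in no class by camera. Ifnb1, the gene of interferon beta, had 0 UMIs in every library, which allows up to 3 in each.

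**Figure D2:**
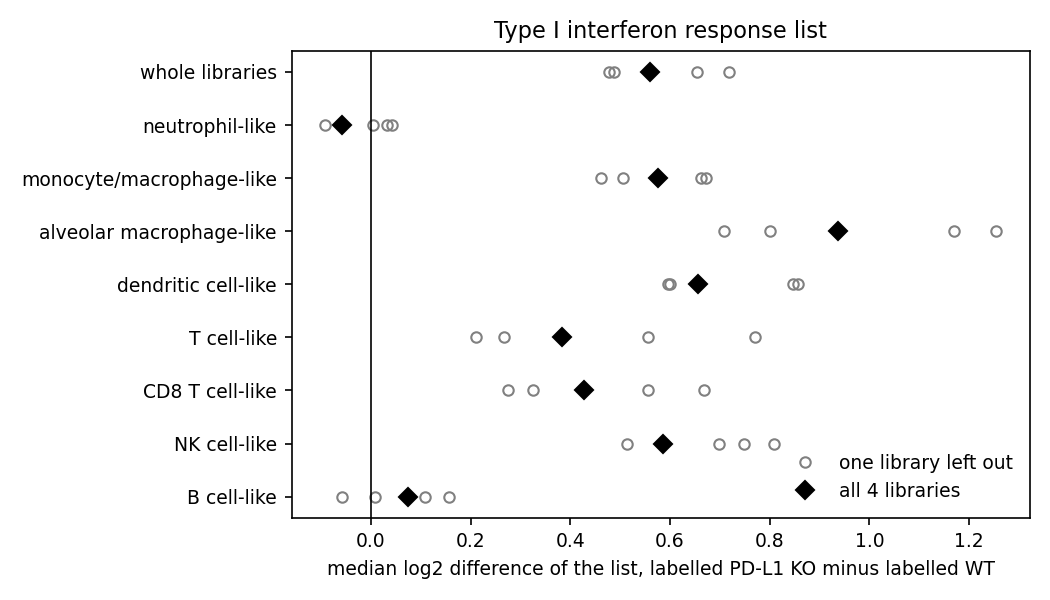
Median log2 difference (x axis, labelled PD-L1 KO minus labelled WT) of the type I interferon response list per fit (y axis); diamonds use all 4 libraries and open circles leave out 1 library each. The median lies above 0 in 8 fits and at -0.06 in neutrophil-like cells, and is highest in alveolar macrophage-like cells (0.94).

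In neutrophil-like sums (453, 267, 285 and 398 cells), secondary granule genes and MHC class II genes were higher in the libraries labelled PD-L1 KO. Few cells carried the granule genes Ltf, Camp and Ngp: 21, 8, 21 and 36 cells held any UMI of them. In library 1 labelled PD-L1 KO a single cell held 1479 of their 2481 UMIs, and in library 2 a single cell held 798 of 1355. Ltf, the granule protein lactoferrin (chromosome 9, 111019271 to 111042767, plus strand), rose from 2.91 CPM ± 4.11 (SD, n = 2) to 238 ± 70.9 (log2 6.03, SE 0.48, edgeR adjusted p = 0.000241). Ngp rose from 54.9 ± 60.5 to 1375 ± 545 (log2 4.56, SE 0.52, adjusted p = 0.0034) and Camp, a cathelicidin, by 6.70 (SE 0.70, adjusted p = 0.00205). Without library 1 labelled WT, Ltf had 0 counts in that group and was at least 38.1-fold higher against 3 counts in the remaining library, and the log2 difference of Ngp was 6.95. H2-Ab1, an MHC class II chain (chromosome 17, 34257689 to 34269419), rose from 54.5 ± 16.8 to 174 ± 11.1 (log2 1.70, SE 0.24, adjusted p = 0.0224). H2-Aa, H2-Eb1 and Cd74 rose by 1.52, 1.40 and 1.37 (adjusted p = 0.0367 each). With interferon, ribosomal and mitochondrial genes kept in clustering these 4 MHC genes stood at 0.85, 0.73, 0.76 and 0.75, and did not pass (smallest adjusted p = 0.695). The class then held 455, 267, 285 and 401 cells, nearly as many, so these calls depended on which cells were placed in it. The granule list had a median of 0.85 (13 of 14 members higher, camera adjusted p = 4.52e-15; 9 members past adjusted over the list alone, 3 over all genes). MHC class II presentation had a median of 1.40 (7 of 7 higher, 1.13e-12; 6 and 4). Both had an adjusted p = 0.515 with an estimated correlation. The granule median was 1.35 without library 2 labelled PD-L1 KO. By edgeR 7 of 4767 genes passed, all higher, and by DESeq2 6. Without each library in turn, in the order WT 1, WT 2, PD-L1 KO 1 and PD-L1 KO 2, the count was 101, 28, 62 and 19. Of the 7 genes, 0 passed after thinning to the smallest library's cells, and 3, the granule genes, passed with no or a strict cell filter, at Leiden resolution 0.5 and with all genes in clustering.

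In monocyte/macrophage-like cells (352, 295, 401 and 373), interferon-induced genes led the ranking without passing the test. Rsad2 stood at 47.3 CPM ± 2.92 (SD, n = 2) and 101 ± 1.93 (log2 1.14, SE 0.15) and Ifit1 at 30.8 ± 0.517 and 70.2 ± 9.70 (log2 1.24, SE 0.17). Lyve1, a hyaluronan receptor of resident macrophages, stood at 41.2 ± 11.6 and 12.2 ± 1.79 (log2 -1.69, SE 0.24). All 3 had an edgeR adjusted p of 0.226. Isg15, a ubiquitin-like interferon effector, stood at 191 ± 23.5 and 389 ± 20.6 (log2 1.07, SE 0.16, adjusted p = 0.283). Cxcl10, a chemokine for CXCR3-bearing T cells, stood at 118 ± 35.2 and 307 ± 38.4 (log2 1.41, SE 0.23, adjusted p = 0.297). Of the interferon list, 31 members passed adjusted over the list alone and 0 over all genes. By edgeR, 0 of 10582 genes passed, 807 had an unadjusted p under 0.05 (529 by chance). DESeq2 called 8 higher and 8 lower. Without the libraries in turn 1091, 68, 23 and 4 genes passed. Cluster 7, led by F13a1 and Ly6c2, held 32.1% of the class over the pooled libraries labelled WT and 27.3% over those labelled PD-L1 KO. Cluster 3, led by Cxcl9 and C1q genes, held 27.2% and 50.8%. The libraries of a group differed, with 125, 51, 188 and 205 cells in cluster 3 in the same library order. Cxcl9 was higher in 7 of 7 fits, though past in 1. These sizes therefore give the makeup of the class and are not compared.

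In alveolar macrophage-like cells (335, 209, 229 and 244), 8 genes were higher and 0 lower. Counts of this class simulated with no change gave 9 calls. Ccr2, the chemokine receptor of inflammatory monocytes (chromosome 9, 124101950 to 124113557), rose from 18.7 CPM ± 1.77 (SD, n = 2) to 58.8 ± 5.88 (log2 1.66, SE 0.15, edgeR adjusted p = 0.026). Cd52, a small leukocyte surface glycoprotein, rose from 194 ± 33.1 to 424 ± 29.5 (log2 1.15, SE 0.12, 0.0329), and Lgals3bp from 112 ± 12.1 to 210 ± 11.0 (log2 0.93, SE 0.11, 0.0424). Cxcl16, the ligand of CXCR6 on T cells, rose from 17.9 ± 3.69 to 46.3 ± 0.458 (log2 1.37, SE 0.17, 0.0433). Lrg1 (1.58), Clec12a (1.11), Ctsk (0.70) and Lyz2 (0.31) were the others. All 8 were no longer past without library 1 labelled PD-L1 KO. Their log2 differences were then 1.75 for Ccr2, 1.2 for Cd52, 0.87 for Lgals3bp, 1.37 for Cxcl16, 1.75 for Lrg1, 0.98 for Clec12a, 0.78 for Ctsk and 0.29 for Lyz2. Lrg1 (1.40), Cxcl16 (1.36) and Ctsk (0.63) were also not past without library 2. Of the interferon list, 46 of 54 members passed adjusted over the list alone and 1, Lgals3bp, over all genes. MHC class I presentation had a median of 0.56 (19 of 19 higher, camera adjusted p = 3.88e-23; 18 past adjusted over the list alone, 0 over all genes) and MHC class II presentation 0.91 (8 of 8 higher, 2.93e-10; 7 and 0). Each had an adjusted p = 0.515 with an estimated correlation, and the latter median was 0.59 without library 2 labelled WT. By edgeR 8 of 9690 genes passed, by DESeq2 22 higher and 1 lower. The count was 118, 40, 0 and 29 without the libraries in turn. Of the 8 genes, 1 passed at Leiden resolution 2, 2 with all genes in clustering and 4 with doublets kept.

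In dendritic-like cells (86, 92, 90 and 103), chemokines that recruit T cells were higher. The class was made of cluster 21, led by Xcr1 (41, 49, 32 and 32 cells), cluster 22, led by Cd209a (31, 30, 41 and 44), and cluster 29, led by Ccl22 (14, 13, 17 and 27), and differences between the groups in this makeup were not removed. Counts simulated with no change gave 2 calls. Cxcl9, a CXCR3 ligand (chromosome 5, 92321347 to 92328079), rose from 65.9 CPM ± 25.1 (SD, n = 2) to 271 ± 36.9 (log2 2.01, SE 0.24, edgeR adjusted p = 0.0294). Cxcl10 (chromosome 5, 92346638 to 92348889) rose from 10.3 ± 10.9 to 102 ± 28.1 (log2 3.35, SE 0.47, 0.043). Without library 1 labelled WT, 3 counts of Cxcl10 remained in that group and the ratio was 40 (counting limits 13.5 to 195), while the log2 difference was 0.30 (0.983) with interferon, ribosomal and mitochondrial genes kept in clustering. Ccl5, a T cell chemokine, rose from 1073 ± 49.3 to 2220 ± 420 (log2 1.03, SE 0.13, 0.0397). Cd40, a co-stimulatory receptor, rose from 33.8 ± 9.52 to 102 ± 14.8 (log2 1.56, SE 0.23, 0.045). Ms4a4c (1.47), Rgs1 (1.01), Zmynd15 (1.18, a gene leading a mature dendritic cluster), Gbp2b (1.57) and Serpina3g (1.77) also rose, and were not past without library 2 labelled WT (1.37, 1.01, 1.23, 1.55 and 1.52). The list of T cell recruiting chemokines had a median of 0.48 (10 of 13 higher, camera adjusted p = 9.06e-06; adjusted p = 0.515 with an estimated correlation; 0.77 without library 1 labelled WT). Of its members 5 were higher and 1 lower adjusted over the list alone, and 3 over all genes. Of the interferon list, 33 of 54 members passed adjusted over the list alone and 1, Ms4a4c, over all genes. By edgeR 9 of 8061 genes passed, all higher, and by DESeq2 15. Left out in turn, the libraries gave 49, 9, 198 and 23. Of the 9 genes, 0 passed at Leiden resolutions 0.5 and 2 or with interferon, ribosomal and mitochondrial genes kept in clustering, and 2 and 4 with no and a strict cell filter, when Cxcl9 stood at 2.06, 2.01 and 1.04 in the first 3 settings.

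In T-like cells (276, 307, 302 and 159), 19 genes were higher and 0 lower, among them Tnfrsf9, Ly6a, Gzmb and the chemokines Ccl3 and Ccl4. The class held 139, 152, 165 and 85 CD8 T-like and 112, 131, 108 and 48 CD4 T-like cells. It also held 25, 24, 29 and 26 regulatory T-like cells. The CD8 T-like cells came from cluster 9, led by Cxcr6 and Pdcd1 (76, 59, 100 and 53). The others came from cluster 12, with Dapl1 and Lef1 among its leading genes (63, 93, 65 and 32). This makeup was not evened out, and its part in the differences was not tested. In cluster 9 on its own, chosen after the data had been seen, 2 of 4447 genes passed by edgeR, Ly6a and Ifi27l2a. Tnfrsf9, the co-stimulatory receptor 4-1BB and one of the genes leading the regulatory T-like cluster (chromosome 4, 150914562 to 150946102), rose from 13.6 CPM ± 11.8 (SD, n = 2) to 69.1 ± 2.21 (log2 2.36, SE 0.34, edgeR adjusted p = 0.00367; 3.60 without library 1 labelled WT). Ly6a, an interferon-inducible surface protein (chromosome 15, 74994877 to 74998031), rose from 59.5 ± 22.1 to 222 ± 111 (log2 1.85, SE 0.27, 0.00377). Gzmb, the cytotoxic protease granzyme B (chromosome 14, 56258838 to 56262260), rose from 24.8 ± 10.4 to 90.8 ± 43.8 (log2 1.80, SE 0.31, 0.0157). Penk, the enkephalin precursor (chromosome 4, 4133531 to 4138819), had 0 counts in the libraries labelled WT and 42 in those labelled PD-L1 KO, at least 16.4-fold higher against 3 counts over the group (adjusted p = 0.00367; at least 8.63- and 7.74-fold without libraries 1 and 2 labelled WT). The chemokines Ccl4 and Ccl3 rose by 1.90 and 2.59 (adjusted p = 0.0142 and 0.0207; 2.99 and 4.16 without library 1 labelled WT). Isg20 and Isg15 rose by 1.60 and 1.25 (0.0142 and 0.0207). Ifitm1 (1.85) was not past without library 1 labelled PD-L1 KO (0.77) or without macrophage-rich cells, a setting chosen after the data had been seen (1.78, 0.132), and Pmepa1 (0.97) not without library 2 labelled WT (0.89). The checkpoint list had a median of 0.63 (11 of 14 higher, camera adjusted p = 7.74e-05; adjusted p = 0.515 with an estimated correlation; 0.20 without library 2 labelled WT), with 4 members past adjusted over the list alone and 0 over all genes. Lag3 stood at 25.3 ± 25.1 and 71.0 ± 8.67 and Pdcd1, the gene of PD-1, at 36.0 ± 32.7 and 79.5 ± 15 (adjusted p = 0.296). By edgeR 19 of 7888 genes passed, all higher. DESeq2 called 0, and 663 had an unadjusted p under 0.05 (394 by chance). Without the libraries in turn 142, 27, 109 and 43 passed. Of the 19 genes, 0 passed at Leiden resolution 0.5 and 5 with a strict cell filter.

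In the CD8 T-like clusters (139, 152, 165 and 85 cells), Ifi27l2a, an interferon-induced mitochondrial protein gene (chromosome 12, 103442167 to 103443680), rose from 614 CPM ± 107 (SD, n = 2) to 1530 ± 375 (log2 1.30, SE 0.19, edgeR adjusted p = 0.0183). It was not past without library 2 labelled WT (1.18) or with no cell filter, and stood at -0.11 (0.962) with interferon, ribosomal and mitochondrial genes kept in clustering. The class held fewer cells in the latter settings, 68, 95, 76 and 38 with no cell filter and 61, 90, 64 and 30 with these genes kept. These numbers lay near those of cluster 12 alone (63, 93, 65 and 32) and not those of cluster 9 (76, 59, 100 and 53). Among the genes not passing were Ly6a at 62.9 ± 28.3 and 208 ± 80.4 (log2 1.67, adjusted p = 0.0738) and Gzmb at 40.8 ± 13.9 and 125 ± 54.3 (log2 1.53, SE 0.31, 0.134). The cytotoxic effector list had a median of 0.41 in T-like cells (12 of 15 higher, camera adjusted p = 4.77e-05; adjusted p = 0.522 with an estimated correlation). It was 0.84 without library 1 labelled WT and 0.13, not past, without library 2. In CD8 T-like cells its median was 0.19 (10 of 14 higher, 0.0179; adjusted p = 0.626 with an estimated correlation). It was not past there without library 2 labelled WT (-0.03) or library 2 labelled PD-L1 KO (0.30), and 0.43 and 0.34 without each other library. It was also not past with no cell filter (0.20) or with all genes in clustering (0.17). Gzmb was the member past adjusted over the list alone in both, and over all genes in T-like cells. By edgeR 1 of 6446 genes passed, 470 had an unadjusted p under 0.05 (322 by chance) and DESeq2 called 1. The count was 79, 0, 40 and 23 without each library in turn.

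In NK-like cells (173, 111, 112 and 110), 20 genes were higher and 1 lower. Isg15 (chromosome 4, 156199424 to 156200818) rose from 32.6 CPM ± 8.14 (SD, n = 2) to 130 ± 33.0 (log2 2.02, SE 0.29, edgeR adjusted p = 0.000959) and Cxcl10 from 3.36 ± 4.75 to 156 ± 115 (log2 5.27, SE 0.61, 6.49e-05). Without library 1 labelled WT, Cxcl10 had 0 counts in that group and was at least 22.8-fold higher against 3 counts in the remaining library. Lgals3, a galectin, rose from 164 ± 15.8 to 413 ± 109 (log2 1.37, SE 0.18, 0.00034), but stood at 0.70 (0.249) without cells rich in macrophage UMIs, a setting chosen after the data had been seen. Pmepa1 rose from 23.4 ± 2.54 to 89.3 ± 3.16 (log2 1.92, SE 0.31, 0.00279). Xcl1, a chemokine for cross-presenting dendritic cells, rose by 1.67 (0.00531) and was not past without library 1 labelled PD-L1 KO (0.85), and Ifi44 rose by 3.27 (0.0157) and was not past without library 2 (2.04). Ccnd3, a cyclin, fell by 0.67 (SE 0.15, 0.049) and was not past without library 1 labelled WT (-0.61), library 2 (-0.72) or library 1 labelled PD-L1 KO (-0.58), nor without macrophage-rich cells (-0.63, 0.0724). MHC class II presentation had a median of 1.58 (6 of 6 higher, camera adjusted p = 2.71e-12; adjusted p = 0.515 with an estimated correlation; 5 past adjusted over the list alone, 4 over all genes). That median was 2.49 without library 1 labelled WT and 1.04 without library 1 labelled PD-L1 KO. Macrophage transcripts (C1qa, C1qb, C1qc, Apoe and Lyz2 together) stood at 421, 74.3, 1054 and 417 CPM in the NK-like sums of WT 1, WT 2, PD-L1 KO 1 and PD-L1 KO 2. Their mean was higher in the libraries labelled PD-L1 KO, but WT 1 lay above PD-L1 KO 2. Without macrophage-rich cells the list still passed, with a median of 1.42, as did Cd74 at 1.94 (0.000856) and H2-Eb1 at 2.57 (0.00158), while H2-Aa did not (1.44, 0.262). The cytotoxic list had a median of -0.01 (adjusted p = 0.109). By edgeR 21 of 5343 genes passed and by DESeq2 1. Without the libraries in turn it was 34, 27, 24 and 46. Of the 21 genes, 8 passed with no cell filter and 8 after thinning.

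In B-like cells (192, 177, 200 and 100) no gene passed. The smallest p belonged to macrophage genes: C1qb, a complement component, stood at 24.8 CPM ± 18.4 (SD, n = 2) and 177 ± 109 (log2 2.92, SE 0.44, edgeR adjusted p = 0.0717). Aif1 stood at 18.9 ± 6.62 and 73.1 ± 3.38 (log2 1.90, SE 0.32, 0.0717). Ccl22 had 0 counts in the libraries labelled WT and 24 in those labelled PD-L1 KO, at least 9.67-fold higher against 3 counts over the group, and did not pass (0.0925). The 5 macrophage transcripts together stood at 886, 1204, 2556 and 875 CPM. By edgeR, 0 of 6460 genes passed, 266 had an unadjusted p under 0.05 (323 by chance) and DESeq2 called 0. Leaving out each library in turn gave 0, 17, 95 and 52.

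**Figure D3:**
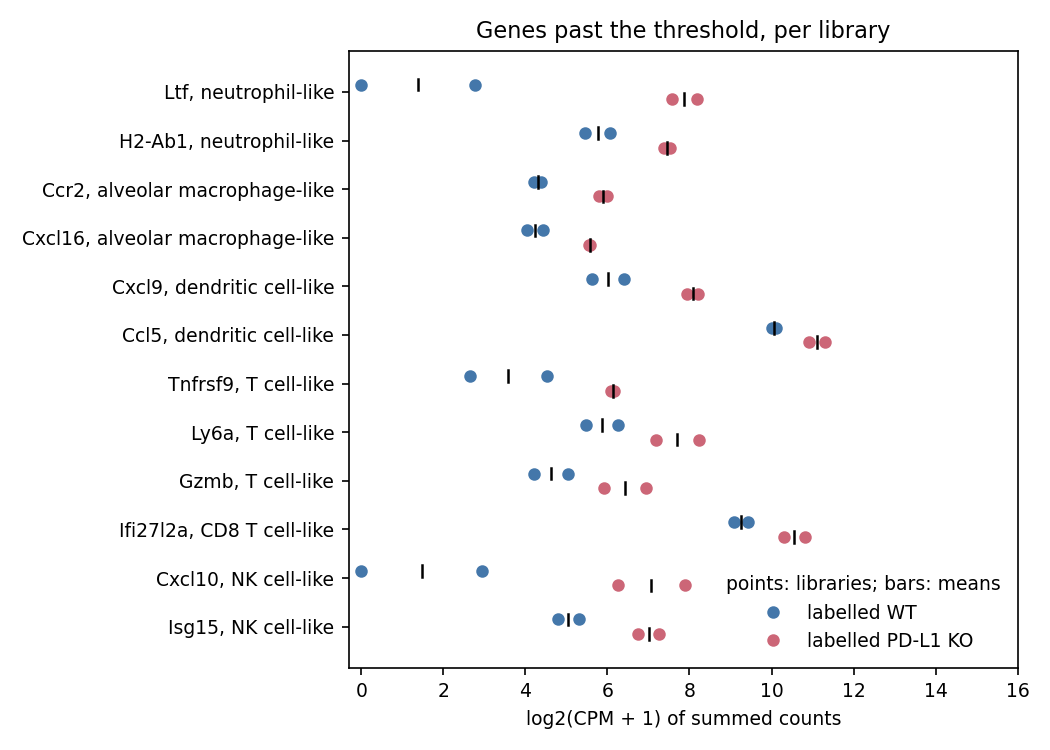
Expression of 12 genes past the threshold (y axis, with the class) as log2(CPM + 1) of summed counts (x axis); points are single libraries coloured by label and bars are means of 2 libraries. For each gene both libraries labelled PD-L1 KO lie above both labelled WT, as the rule for naming requires.

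Among genes followed in every fit, Cd274 was higher in the libraries labelled PD-L1 KO in 8 of 8 fits, by 0.34 in B-like to 1.01 in monocyte/macrophage-like cells. By edgeR 0 passed (smallest adjusted p = 0.267, smallest unadjusted p of 0.00513). Cxcl10 was higher in 8 of 8 fits (1.41 in monocyte/macrophage-like to 5.27 in NK-like cells, 2 past). Cxcl9 was higher in 7 of 7 (0.21 in T-like to 4.63 in B-like cells, 1 past). Gzmb was higher in 6 of 6 (0.04 in NK-like to 1.80 in T-like cells, 1 past). Cd8a was higher in 6 of 6 (0.01 in monocyte/macrophage-like to 2.81 in NK-like cells, 0 past). RNA of other cells was not removed from these sums. Isg15 was higher in 8 of 9 fits, with 2 past. Irf7, the regulator of interferon genes, was higher in 8 of 9 (-0.17 to 1.85, 0 past, smallest adjusted p = 0.170). Ifnar1, a type I interferon receptor chain, was higher in 4 of 9 (-0.64 to 0.41, 0 past). Pdcd1 was higher in 4 of 4 (0.33 to 1.19) and Pdcd1lg2 in 4 of 5, with 0 past for either. Ccl5 was higher in 5 of 9 (-0.96 in B-like to 1.89 in alveolar macrophage-like cells, 1 past). Arg1 was higher in 2 of 3 and S100a8 in 4 of 9 (-1.55 in NK-like to 1.69 in B-like cells). Ptprc, the gene of CD45, was higher in 1 of 9 and Xist in 2 of 9 (-0.25 to 0.19), with 0 past for the last 4 genes.

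Of the other lists, interferon-gamma-inducible GTPases and regulators ranked higher in 8 of 9 fits by camera (medians 0.01 to 0.94), with 32 members higher and 1 lower adjusted over the list alone and 0 over all genes. Without the libraries in turn 8, 6, 8 and 5 of these calls held. MHC class I presentation ranked higher in 8 of 9 (0.07 to 0.56; 30 and 0 members; 8, 7, 8 and 7 held) and MHC class II presentation in 7 of 9 (-0.12 to 1.58; 28 and 9; 7, 6, 6 and 7 held). T cell recruiting chemokines ranked higher in 6 of 9 (0.07 to 1.59; 26 higher and 5 lower, and 8; 6, 4, 4 and 6 held). Checkpoint genes did so in 4 of 9 (-0.13 to 0.63; 7 and 0; 4, 3, 3 and 4 held) and cytotoxic effectors in 3 of 7 (-0.01 to 1.01; 5 and 1; 3, 1, 3 and 1 held). For glycolysis it was 8 of 9 (-0.07 to 0.44; 6 and 0; 8, 3, 8 and 4 held) and for oxidative phosphorylation 8 of 9 (0.10 to 0.29; 1 and 0; 8, 6, 8 and 5 held). For proliferation it was 6 of 9 (-0.09 to 0.81; 5 and 0; 5, 4, 4 and 5 held). Suppressive myeloid genes ranked higher in 7 of 9 (0.17 to 1.72; 18 higher and 2 lower, and 1; 6, 4, 6 and 6 held). Of these calls 4 were in T-, CD8 T-, NK- and B-like cells, and neutrophil-like (0.29, adjusted p = 0.114) and monocyte/macrophage-like sums (0.31, 0.157) did not pass. Without macrophage-rich cells, the medians were 0.47 in T-like and 0.24 in CD8 T-like cells, both past, and 0.20 (0.275) in NK-like and -0.14 (0.612) in B-like cells, not past, against 0.58, 1.03, 1.72 and 0.91 with them. The NK-like median was 3.42 and 0.21 without libraries 1 and 2 labelled WT, and 1.04 and 1.71 without libraries 1 and 2 labelled PD-L1 KO. Inflammatory and NF-kB genes ranked higher in 4 of 9 (-0.13 to 0.37; 3 and 0; 3, 4, 1 and 4 held). Granule genes did so in 3 of 8 (3, 3, 3 and 2 held) and myeloid chemokines in 2 of 8 (0.00 to 0.49; 17 higher and 1 lower, and 2; 1, 2, 1 and 2 held). All of these calls were lost with an estimated correlation (smallest adjusted p = 0.515 with an estimated correlation).

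Immediate early and heat shock genes ranked lower in 9 of 9 fits (medians -0.29 to -0.11, 14 members lower and 2 higher adjusted over the list alone, 0 over all genes). Without the libraries in turn 5, 8, 9 and 4 of these held. Fosb, an early response transcription factor induced by tissue handling among other stimuli, stood at 498 CPM ± 94.2 (SD, n = 2) and 259 ± 38.2 in monocyte/macrophage-like cells (log2 -0.89, SE 0.18, edgeR adjusted p = 0.461). Ribosomal protein genes ranked higher in neutrophil-like cells (median 0.30, 19 members past adjusted over the list alone, 0 over all genes). They also did in whole libraries (0.07; -0.02 over leukocyte clusters alone, chosen after the data had been seen; not past without library 2 labelled WT, 0.02, or library 2 labelled PD-L1 KO, 0.06; 0.12 without library 1 labelled WT). They ranked lower in dendritic-like (-0.08) and T-like cells (-0.06). In T-like cells the direction turned without library 2 labelled WT (0.04, adjusted p = 0.0249), the list was not past without either library labelled PD-L1 KO (-0.03 and -0.07) or at Leiden resolutions 0.5 and 2 (-0.03 and -0.05), and its median was -0.18 without library 1 labelled WT. Mitochondrial transcripts ranked higher in 1 fit and lower in 2 of 9 (-0.10 to 0.31). Of these 0 and 2 held without library 1 labelled WT, 1 and 0 without library 2, 1 and 1 without library 1 labelled PD-L1 KO, and 0 and 1 without library 2. Lung epithelial genes ranked lower in monocyte/macrophage-like cells (-0.52, adjusted p = 0.0292), but were not past without library 2 of either label (-0.36 and 0.43), with -1.30 and -0.85 without library 1 of each, nor with a strict cell filter (0.18) or at Leiden resolution 2 (-0.05), and did not pass in whole libraries (-0.71, 0.256). There the median was -1.38 (0.015) without library 1 labelled WT, 0.37 (0.994) without library 2, -2.07 (0.00146) without library 1 labelled PD-L1 KO and 0.47 (0.264) without library 2. Immunoglobulin genes passed in 0 of 4 fits (smallest adjusted p = 0.0919, in B-like cells, with a median of 0.00). In B-like cells they passed without each library in turn, but in both directions, at 0.75 (6.81e-05), -0.46 (1.13e-24), 0.43 (1.54e-12) and 0.12 (1.25e-09) without WT 1, WT 2, PD-L1 KO 1 and PD-L1 KO 2. They also passed at -0.11 (0.000406) in whole libraries without WT 2, -0.65 (0.00182) in monocyte/macrophage-like cells without WT 1, and 1.23 (0.000781) and 0.87 (0.00014) in dendritic-like cells without WT 2 and PD-L1 KO 1. Haemoglobin genes, tested in whole libraries, had a median of 1.76 (0.117). It was -0.18 (0.221) without library 1 labelled WT, 3.82 (1.04e-14) without library 2, 1.83 (0.146) without library 1 labelled PD-L1 KO and 1.60 (0.0476) without library 2. No call in this group held with an estimated correlation (smallest adjusted p = 0.515 with an estimated correlation).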

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

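Of the tests in this part, the comparison of alveolar macrophage-like cells with 1 monocyte cluster and the tests of macrophage and neutrophil RNA, cluster proportions, exchanged labels and doublets were chosen after the result was seen.

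MHC class II genes moved apart in the alveolar macrophage-like class and in cluster 7, a monocyte-like cluster led by Ly6c2 and F13a1. With each library as a block, the list's difference between the labelled groups was higher by a median of 1.61 on the log2 scale in alveolar macrophage-like cells (9 members, camera adjusted p = 3.7e-27; adjusted p = 0.162 with an estimated correlation). H2-Ab1, an MHC class II chain, differed by 2.09 (SE 0.17, edgeR adjusted p = 2.65e-07), H2-Eb1 by 2.18 (1.46e-06) and Cd74, the invariant chain, by 1.67 (6.58e-07), while H2-DMa, a peptide-loading chain, differed by 0.31 (0.951). The difference itself passed for 34 of 9498 genes. The type I interferon list also differed between these cells, by 0.89 (3.16e-29; adjusted p = 0.244 with an estimated correlation). As the comparison was chosen from these same counts after the result was seen, its p-values carry that choice. It was not repeated without each library. No explanation was tested for this pattern.

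The type I interferon response list ranked higher in the T-like, NK-like and monocyte/macrophage-like sums of the libraries labelled PD-L1 KO, by 1612, 1219 and 1922 CPM over its members together, but each camera call was lost with an estimated correlation (adjusted p = 0.515 with an estimated correlation). RNA of macrophages and neutrophils was scaled by C1qa, C1qb and C1qc in the monocyte/macrophage-like class and by S100a8 and S100a9 in the neutrophil-like class. At its upper counting limit it would bring 6.8% of the difference in T-like and 12.7% in NK-like cells. That argues against RNA of these classes, in their own mix of cells, as the whole cause there. RNA of alveolar macrophage-like, dendritic-like or other cells, or of single clusters low in C1q genes, was not covered. An earlier form of the test with C1q scaling alone, over 4 classes, had decided nothing. In B-like cells, where the list did not pass, RNA of macrophages and neutrophils would bring 113% of the difference. Other proportions of the 4 monocyte/macrophage-like clusters at their levels in the libraries labelled WT would bring -161 CPM, or -8.4% of the difference, which argues against them as its whole cause, although the list's median was 0.0065 in cluster 14 and 0.13 in cluster 7, against 0.63 and 0.68 in clusters 3 and 16. Exchanged labels cannot be told apart from the labels as given, because 14 carcinoma-like cells hold too few Cd274 UMIs, 6 of them in 1 cell that also held 24 Ptprc UMIs, and would turn every direction in the text. A response of these cells to tumour cells with and without PD-L1 may underlie the pattern, but remained untested, as did differences between mice or captures.

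C1qa, C1qb, C1qc, Apoe and Lyz2, which macrophages express strongly, had a higher mean in the libraries labelled PD-L1 KO in NK-like (421 and 74.3 against 1054 and 417 CPM) and B-like sums (886 and 1204 against 2556 and 875 CPM), but library 2 labelled PD-L1 KO lay below library 1 labelled WT in both, and without library 1 labelled PD-L1 KO the B-like difference turned. Free RNA alone was taken to give T-, NK- and B-like cells of a library 1 level. The highest of them lay 16.196 times above the lowest in library 2 labelled WT, beyond counting limits. It lay 4.17 and 2.86 times above in the libraries labelled PD-L1 KO, also beyond them, and 2.10 times in library 1 labelled WT. These sums include cells with at least 10 such UMIs, and median UMIs per cell differed (3999.5 in T-, 2902 in NK- and 2813 in B-like cells). The ratios therefore do not decide on free RNA in the remaining cells. Over all libraries, cells with at least 10 of these UMIs held 77.8% of them in NK-like and 74.2% in B-like cells. Macrophage doublets may thus account for the NK-like level, while the B-like share fell between the limits and decided nothing. These outcomes rest on pooling. The shares in libraries labelled WT and PD-L1 KO were 68.4% and 82.5% in NK-like cells, and 65.1% and 80.1% in B-like cells. The limit of 75% had first been set for both classes together and was split once the shares were known, and 10 of 506 NK-like cells carry the NK-like result. Uptake of macrophage material by lymphocytes stayed open and was not tested.

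Ltf, Camp and Ngp, made by immature neutrophils for their secondary granules, rose in neutrophil-like sums of the libraries labelled PD-L1 KO. In these libraries their mean level in any other tested class reached at most 0.06% of that in neutrophil-like cells, which argues against free RNA from other cells there. Monocyte/macrophage-like cells of library 2 labelled WT stood at 14.1 CPM, from 34 UMIs in 2 cells, against 16.2 CPM in its neutrophil-like cells. The 5% of neutrophil-like cells with the most of these UMIs held 99.7% and 98.8% of them in libraries 1 and 2 labelled PD-L1 KO, and single cells held up to 1479 and 798 of the 2481 and 1355 UMIs. A few immature cells may therefore account for the calls, with 21 and 36 cells holding any such UMI against 21 and 8 in the libraries labelled WT, where 103 and 8 UMIs were found. Whether release of immature neutrophils from the marrow differed between the groups was not tested.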

How the results depend on the processing

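In this part the crossed pairing, leukocyte clusters alone, clusters fitted on their own, clustering without differing genes, removal of macrophage-rich cells and the label check under other settings were chosen after the result was seen; the other settings were not. Unless a cause is named, the cause of a change was not tested.

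With 2 libraries per group the number of gene calls changed with which library was present. The lone library of a group is assumed to vary like the others when 1 is left out. Genes past edgeR's test then ranged from 0 to 2258 in whole libraries, 19 to 101 in neutrophil-like, 4 to 1091 in monocyte/macrophage-like, 0 to 118 in alveolar macrophage-like, 9 to 198 in dendritic-like, 27 to 142 in T-like, 0 to 79 in CD8 T-like, 24 to 46 in NK-like and 0 to 95 in B-like cells, and from 216 to 1614 over the classes, against 65 with all libraries. Of 53 genes named as past the threshold, 50, 44, 37 and 44 stayed past without libraries 1 and 2 labelled WT and 1 and 2 labelled PD-L1 KO, 53 with DESeq2's size factors or no low-count filter, 49 with doublets kept, 34 after thinning (17 lost), 31 with the strict cell filter (19 lost), 28 with no cell filter, 35 and 25 at Leiden resolutions 2 and 0.5 (18 and 27 lost), 30 with all genes in clustering and 23 by DESeq2. Genes neither kept nor lost had no value there. Shares of cell classes passed under no setting run (smallest adjusted p = 0.0674, with the crossed pairing). In the label check, Cd274 kept its direction in each fit run, by 12.2 to 19.6 CPM. CD8 T-like clusters could not be formed with the strict cell filter or at Leiden resolution 0.5, so they have no value there. In simulated counts, 45%, 53%, 48% and 35% of 2-fold changes were recovered in dendritic-, CD8 T-, NK- and B-like sums, against 36% in the deeper whole libraries.

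Called lists numbered 99. With an estimated correlation 0 passed, and with fry 1. These tests do not change the medians of the interferon list, but it lost its calls. The medians were 0.56 in whole libraries, 0.58 in monocyte/macrophage-like, 0.94 in alveolar macrophage-like and 0.66 in dendritic-like cells. They were 0.38 in T-like, 0.43 in CD8 T-like and 0.59 in NK-like cells. In each the adjusted p = 0.515 with an estimated correlation, and 0.381 to 0.612 by fry. In simulated counts with genes drawn independently, the list was shifted by 0.5 on the log2 scale. With an estimated correlation camera then gave unadjusted p = 0.00346 in alveolar macrophage-like to 0.045 in NK-like cells. With the preset correlation it gave 2.21e-48 and 1.48e-15. In the fits that had passed, the real list had unadjusted p = 0.0281 in monocyte/macrophage-like to 0.16 in T-like cells by camera with an estimated correlation. Each was above the simulated value of the same fit. As the simulated genes were drawn independently, the simulation cannot tell whether a lost call means an unshifted list. Of the 99, 90, 71, 86 and 73 held without the libraries in turn, 99 with DESeq2's size factors, 93 with doublets kept, and 83 with no cell filter. Fewer lists had a value in the next settings, as whole libraries do not change with the clustering and CD8 T-like cells were absent in 2 of them. Calls kept, no longer past and turned were 74, 11 and 2 with the strict filter, 75, 8 and 0 at Leiden resolution 2, 67, 4 and 0 at resolution 0.5, and 67, 13 and 3 with all genes in clustering.

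With libraries left out in turn, the interferon median ranged from -0.092 to 0.043 in neutrophil-like and -0.059 to 0.16 in B-like cells. In neutrophil-like cells mitochondrial transcripts ranged from -0.073 to 0.63. In monocyte/macrophage-like cells inflammatory and NF-kB genes ranged from -0.0086 to 0.56, glycolysis from -0.0021 to 0.82, lung epithelial genes from -1.30 to 0.43 and Arg1 from -0.75 to 1.61. In alveolar macrophage-like cells T cell recruiting chemokines ranged from -0.12 to 1.86, myeloid chemokines from -0.029 to 0.69 and NF-kB genes from -0.019 to 0.54. Oxidative phosphorylation in B-like cells ranged from -0.0099 to 0.35, T cell recruiting chemokines and ribosomal proteins in T-like cells from -0.040 to 1.48 and -0.18 to 0.041, cytotoxic and checkpoint genes in CD8 T-like cells from -0.030 to 0.43 and -0.031 to 0.83, and S100a8 in cluster 7 from -1.29 to 1.27.

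DESeq2 called 15 genes in whole libraries, 16 in monocyte/macrophage-like, 23 in alveolar macrophage-like, 15 in dendritic-like, 0 in T-like and 1 in NK-like cells. Without the low-count filter more genes with few counts were tested, and 60 passed in neutrophil-like, 63 in monocyte/macrophage-like, 338 in alveolar macrophage-like, 171 in dendritic-like, 58 in T-like, 37 in CD8 T-like, 56 in NK-like and 35 in B-like cells, 818 in all. Thinning to the smallest library's cells, which leaves fewer cells, gave 0 in neutrophil-like, 21 in alveolar macrophage-like, 5 in CD8 T-like and 8 in NK-like cells. With doublets kept there were 12 in neutrophil-like, 21 in alveolar macrophage-like and 15 in dendritic-like cells.

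With no cell filter 3 genes passed in neutrophil-like, 3 in dendritic-like, 0 in CD8 T-like and 8 in NK-like cells, 43 in all. The interferon median was then -0.13 in neutrophil-like (adjusted p = 0.0396), 0.10 in CD8 T-like (0.056) and -0.023 in B-like cells. The CD8 T-like class held 68, 95, 76 and 38 cells in this setting, against 139, 152, 165 and 85. These numbers lay near those of cluster 12 alone (63, 93, 65 and 32). The median of suppressive myeloid genes was -0.046 in dendritic-like cells and -0.16 in CD8 T-like cells, where T cell recruiting chemokines were at -0.041, checkpoint genes at -0.46 and proliferation genes at -0.040, and S100a8 in T-like cells was at 1.31 (0.00825). With the strict filter 33 genes passed in alveolar macrophage-like, 5 in T-like and 1 in B-like cells. Lung epithelial genes were then at 0.18 in monocyte/macrophage-like cells, and the interferon list at -0.24 and suppressive genes at -0.71 in B-like cells.

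With interferon, ribosomal and mitochondrial genes kept in clustering, 12 genes passed in neutrophil-like, 2 in alveolar macrophage-like, 0 in dendritic-like and 0 in CD8 T-like cells. The interferon median was 0.090 in neutrophil-like and 0.019 in CD8 T-like cells (0.251), where T cell recruiting chemokines were at -0.055, checkpoint genes at -0.52 (0.0161), proliferation genes at -0.11 and Ifi27l2a at -0.11. The CD8 T-like class held 61, 90, 64 and 30 cells here, near the numbers of cluster 12 alone (63, 93, 65 and 32). Its values are therefore for another, smaller set of cells. Leiden resolution 2 gave 2 genes in alveolar macrophage-like and 0 in dendritic-like cells, and resolution 0.5 gave 0 in dendritic-like, 0 in T-like and 4 in B-like cells, 41 in all. Without cells rich in macrophage UMIs 14 genes passed in CD8 T-like cells, and the medians in B-like cells were -0.11 for interferon and -0.14 for suppressive genes. In whole libraries of leukocyte clusters alone, 0 of 12702 genes passed by edgeR (1468 at an unadjusted p under 0.05, 81 higher and 9 lower by DESeq2), and ribosomal proteins were at -0.021.

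Libraries share only a number across the groups: the deviations of same-numbered libraries correlated at -0.372 over whole libraries and -0.273 to 0.00789 in the classes. With the number as a replicate block, 3 genes passed in neutrophil-like, 19 in monocyte/macrophage-like, 13 in alveolar macrophage-like, 42 in T-like, 16 in CD8 T-like, 49 in NK-like and 1 in B-like cells, 155 in all, and all 99 list calls were kept. The 3 in neutrophil-like cells were the granule genes, while H2-Ab1, H2-Aa, H2-Eb1 and Cd74 stood at 1.76, 1.56, 1.44 and 1.43 (0.101 to 0.152). In clusters 7, 9 and 16, 9, 12 and 1 genes passed, among them 8 of 10, 2 of 2 and 1 of 15 called without the block. The crossed pairing as a block gave 99 genes in neutrophil-like, 241 in alveolar macrophage-like, 163 in dendritic-like, 44 in T-like, 76 in CD8 T-like and 5 in B-like cells, 651 in all, and 108 lists.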

Other observations

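Tests of clusters on their own and removal of macrophage-rich cells were chosen after the result of the classes was seen, and no explanation is offered for their values.

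In cluster 7, Ly6c2-high monocyte-like cells, 5 genes rose and 5 fell in the libraries labelled PD-L1 KO. Cxcl10, a chemokine for CXCR3-bearing T cells, rose from 9.43 CPM ± 8.41 (SD, n = 2) to 86.8 ± 43.4 (log2 3.30, SE 0.45, edgeR adjusted p = 0.00218), and Cxcl1, a neutrophil chemokine, from 10.2 ± 1.34 to 55.2 ± 9.96 (log2 2.45, SE 0.34, 0.00234). Mt1, a metallothionein, Ly6a and Chil3 rose by 1.28, 2.50 and 0.90 (0.00364, 0.0227 and 0.0433). H2-Eb1 fell from 1148 ± 69.9 to 563 ± 82.7 (log2 -1.01, SE 0.13, 0.00172), and H2-Ab1, Cd74, Fosb and H2-Aa fell by 0.91, 0.78, 0.78 and 0.71 (0.00172, 0.0108, 0.0433 and 0.0433). MHC class II presentation had a median of -0.76 (1 of 8 members higher, camera adjusted p = 3.23e-17; adjusted p = 0.589 with an estimated correlation; 6 members lower adjusted over the list alone, 4 over all genes). Inflammatory and NF-kB genes had a median of 0.18 (12 of 16 higher, 0.00187; adjusted p = 0.591 with an estimated correlation; 2 past adjusted over the list alone, 0 over all genes). By edgeR 10 of 6919 genes passed and by DESeq2 5, while without libraries 1 and 2 labelled WT 0 and 3 passed and without libraries 1 and 2 labelled PD-L1 KO 42 and 48. Not 1 of the 10 passed without library 1 labelled WT, when Cxcl10 stood at 2.51, Cxcl1 at 2.30, Mt1 at 1.23, Ly6a at a ratio of 8.56 (counting limits 2.79 to 42.7, on 3 counts), Chil3 at 1.06, H2-Eb1 at -0.96, H2-Ab1 at -0.84, Cd74 at -0.75, Fosb at -0.72 and H2-Aa at -0.60. Without library 2 Cxcl10 passed, with 3 counts left in that group and a ratio of 25.6 (counting limits 8.59 to 126), but not Cxcl1 (2.58), Mt1 (1.33), Ly6a (2.15), Chil3 (0.76), H2-Eb1 (-1.07), H2-Ab1 (-0.98), Cd74 (-0.83), Fosb (-0.84) or H2-Aa (-0.82).

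In cluster 16, macrophage-like cells led by Folr2 and Ccl8, 9 genes rose and 6 fell. Iigp1, an interferon-inducible GTPase, rose from 22 CPM ± 14.2 (SD, n = 2) to 118 ± 6.09 (log2 2.56, SE 0.34, edgeR adjusted p = 0.000401), and Ly6e by 1.11 (0.0339), which was not past without library 1 labelled WT (0.92). Zbp1, a nucleic acid sensor, Ifi27l2a and AW112010 rose by 1.60, 0.72 and 1.11 (0.0111, 0.0375 and 0.0418) and were not past without library 2 labelled WT (1.41, 0.63 and 0.74). Irf7 rose by 1.34 (0.0331) and was not past without library 2 labelled WT (1.24) or library 1 labelled PD-L1 KO (0.94), and Cdkn1a by 1.06 (0.0418), not past without these or library 1 labelled WT (1.11, 0.76 and 1.01). Gzma, a granzyme of lymphocytes, rose by 2.17 (0.0368), with 4.46 without library 2 labelled WT and 1.41 without library 2 labelled PD-L1 KO. Chil3, Ear2 and Lpl, which alveolar macrophages express, fell by 3.22, 2.67 and 1.64 (0.000301, 0.000393 and 0.00548), and Retnlg, a neutrophil gene, by 1.44 (0.00634). Plet1 and Slc7a2 also fell (0.000401 each), with 3 counts and 1 count in the libraries labelled PD-L1 KO, so that the ratios were 17.5 (counting limits 5.75 to 86.6) and 48.2 (8.37 to 1932). Without library 2 labelled PD-L1 KO, Slc7a2 had 0 counts in that group and was at least 10-fold lower against 3 counts in the remaining library. Neutrophil granule genes had a median of -0.78 (0 of 8 higher, camera adjusted p = 1.73e-08; adjusted p = 0.589 with an estimated correlation; 3 lower adjusted over the list alone, 2 over all genes). The interferon list had a median of 0.68 (50 of 53 members higher, camera adjusted p = 3.26e-21; adjusted p = 0.589 with an estimated correlation; 14 members adjusted over the list alone, 4 over all genes). By edgeR 15 of 6641 genes passed and by DESeq2 3, and 54, 26, 85 and 100 without the libraries in turn.

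In cluster 9, CD8 T-like cells led by Pdcd1 and Cxcr6, Ly6a rose from 29.6 CPM ± 7 (SD, n = 2) to 249 ± 53.2 (log2 3.00, SE 0.32, edgeR adjusted p = 0.000277) and Ifi27l2a from 809 ± 38.1 to 2212 ± 485 (log2 1.45, SE 0.18, 0.00111). Both were not past without library 2 labelled PD-L1 KO (2.80 and 1.22), and 2 of 4447 genes passed by edgeR and 2 by DESeq2, with 34, 20, 25 and 0 without the libraries in turn. MHC class II presentation had a median of 1.16 (6 of 6 higher, camera adjusted p = 4.95e-08; adjusted p = 0.589 with an estimated correlation; 5 past adjusted over the list alone, 0 over all genes). Mt1 was the 1 gene past in cluster 14, at 2.85 (0.0197), where DESeq2 called 0. Without library 1 labelled WT, 2 counts of Mt1 remained in that group and the ratio was 34.8 (counting limits 9.36 to 292). In the other splits of the 4 libraries, 0 and 4 genes passed in cluster 14, 0 and 4 in cluster 16, 2 and 2 in cluster 7 and 0 and 2 in cluster 9. List tests of single clusters were not repeated without each library.

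Removal of cells with at least 10 macrophage UMIs left 15 of the 19 genes past in T-like cells and 14 of the 21 in NK-like cells. It took out 45 of 1044 T-like, 25 of 541 CD8 T-like, 10 of 506 NK-like and 59 of 669 B-like cells. Among NK-like genes no longer past, the log2 difference of Apoe went from 2.27 to 0.80, that of Ctss from 1.80 to 0.28 and that of Lgals3 from 1.37 to 0.70, whereas H2-Aa went from 1.72 to 1.44 and Ccnd3 from -0.67 to -0.63. Cd74 and H2-Eb1 stayed past in NK-like cells, at 1.94 and 2.57. Of the lists called in these 4 classes, 33 still passed, 5 no longer did and 1 turned. Among T-like genes no longer past, Cd74 went from 1.17 to 1.38 and Ifitm1 from 1.85 to 1.78. In NK-like cells 20.8% of cells in the libraries labelled WT and 29.7% in those labelled PD-L1 KO held any of these UMIs, and in T-like cells 29.2% and 38.2%.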
